A study of Bos taurus with 34 samples.

How the data were processed

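Bovine embryonic stem cell (bESC) lines are self-renewing cultures grown from whole blastocysts on a layer of mouse feeder cells. Per the labels, they came from embryos made by in vitro fertilization (IVF), by somatic cell nuclear transfer (SCNT, in which the nucleus of a body cell replaces that of an egg) and by parthenogenesis (PAR, activation of an egg without sperm). RNA was profiled by 3' tag sequencing, which reads one end of each transcript, so that a count does not grow with transcript length. Per the labels' protocols, RNA was taken from fibroblasts and from bESC freed of feeder cells, and single-end reads of 90 bp were made. There were 3 IVF lines, 3 SCNT lines, 1 PAR line and 3 fibroblast cultures, 10 RNA libraries in all. The series also lists 24 CUT&Tag samples, a chromatin assay of histone marks, which were not analysed here.

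The deposited values were whole-number counts per gene and library, made by the authors and not normalized. The submitters' processing notes name STAR 2.7.2a, HTSeq 0.10.0, UMI-tools 1.0.0, SAMtools 1.9 and the bovine build ARS-UCD1.2, without saying which step used what. Whether duplicate molecules were collapsed, whether strand was used in counting and which annotation release was taken are not given in the sources used here. Counting intervals and floors therefore cover counting error only, and overlapping or antisense genes and near-identical copies cannot be told apart in these counts. Each table listed 27607 gene IDs and closed with 5 lines that name no gene. Those lines were kept out of library sizes and tests. Reads outside any gene made up 31.3% to 40.8% of the counts on gene and closing lines.

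Gene totals ran from 1630981 to 2234356 counts per library, so 1 count stood for at most 0.613 CPM (counts scaled to a common library total). A gene at 3 counts or fewer in a library was taken as at the floor there, and a gene at 10 CPM or more as expressed. The reference table holds 37063 bovine genes of another assembly, ARS-UCD2.0, and 0 of the IDs matched a symbol in it. The files do not pair IDs with names either. The 33 gene lists fixed before the data were examined and the rule for named genes both rest on symbols and could not be used. In their place, the rule was applied without its condition on symbols: adjusted p under 0.05, a mean of at least 10 CPM in the higher group, no overlap between the libraries compared, and the largest log2 fold changes, with at most 2 IDs printed per direction. Classes of genes were described instead, by where they were expressed or at the floor.

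Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, a group-means model over all 10 libraries, robust quasi-likelihood fits with 6 residual degrees of freedom, and Benjamini-Hochberg adjustment at 0.05. Genes with at least 1 CPM in at least 3 libraries were kept, which left 13800. CPM behind gene classes and genes at the floor in 1 line alone used library totals without TMM. CPM of the IDs printed by the rule included it. The common biological coefficient of variation was 0.337. Standard errors were taken from the quasi-likelihood F. Comparisons were the mean of the IVF and SCNT groups against fibroblasts, SCNT against IVF, each of these against fibroblasts, and PAR against IVF. The PAR line had no replicate, so its test assumed that it varies like the other groups. A fibroblast score was computed per library as the mean log2 CPM (prior count 2) of genes called higher in fibroblasts minus that of genes called higher in bESC lines, and compared between SCNT and IVF lines by an exact permutation test, which cannot go below p = 0.1 with 3 against 3. The labels call the lines of a group replicates. Where nothing says that they came from separate embryos or donors, p-values measure only the spread between these samples.

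No library pair was identical, and within groups the counts differed by at least 3.53 times the sampling variance, so no library was counted as a duplicate. On simulated counts for 13800 genes, the SCNT against IVF test recovered 19.4%, 71.6% and 89.4% of genes changed by 1, 2 and 3 on the log2 scale, with 12 false calls. For bESC lines against fibroblasts the shares were 32.8%, 85.1% and 92.4%, with 10 false calls. For PAR against IVF they were 4.48%, 41.8% and 74.2%, with 4 false calls. The changed genes were drawn only from genes whose mean count lay well above the floor, so recovery of genes with lower counts was not measured. A single simulated data set without any change gave 0 calls in each comparison. Alternatives were median-of-ratios scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1) and no filter on low counts. Others were a fit of only the groups compared, the replicate number as a block, each replicate left out, and a baseline of IVF and SCNT lines for PAR. The last was the nuclear donor's fibroblast library alone as a baseline for SCNT. No label names the donor, and fibroblast replicate 1 was taken as the donor from the series text read with the sample list. These choices were made before the data were examined.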

Results

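The 10 RNA libraries came from 3 IVF lines at passage 8, 3 SCNT lines at passage 8, 1 PAR line at passage 10 and 3 fibroblast cultures at passage 7. Per the labels the IVF and SCNT lines were male, the PAR line was female, and fibroblast replicate 3 was female while replicates 1 and 2 were male. Totals of counts on genes were 1803800 ± 67367 (SD, n = 3) for IVF, 1729046 ± 130902 (n = 3) for SCNT, 1846370 ± 141863 (n = 3) for fibroblasts and 2234356 for PAR. Genes detected per library numbered 14477 to 15053 in IVF, 13756 to 14262 in SCNT, 14778 in PAR and 13305 to 13553 in fibroblasts, so the IVF and SCNT ranges did not overlap. Across genes, log2 CPM correlated at 0.946 to 0.959 within the IVF group, at 0.957 to 0.966 within the SCNT group and at 0.895 to 0.935 within the fibroblasts. Genes are not independent replicates, and these correlations only describe the libraries.

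**Figure D1:**
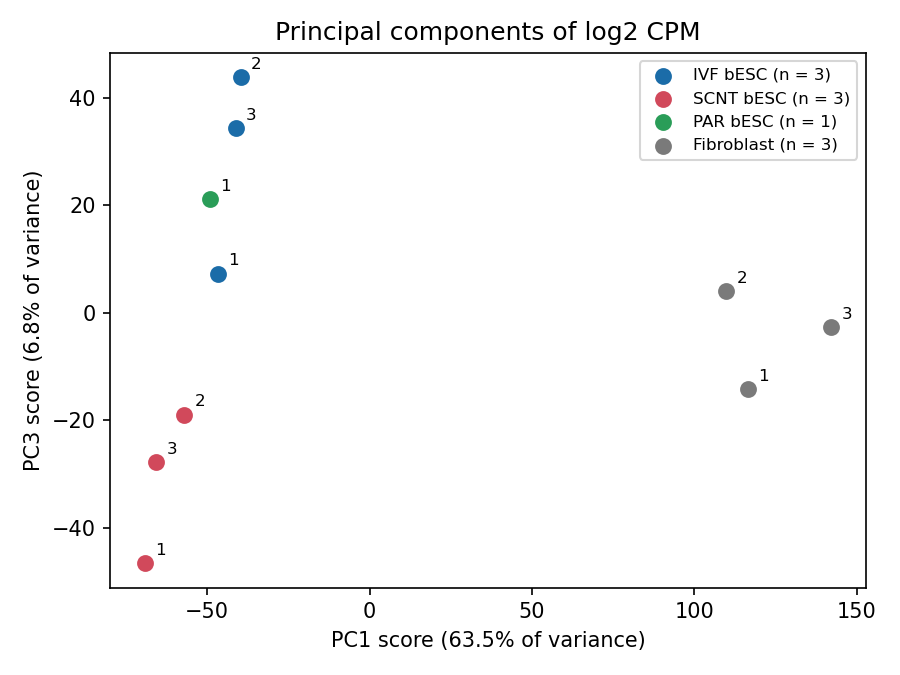
Scores of the 10 libraries on the first principal component (x axis, 63.5% of variance) and the third (y axis, 6.84%) of log2 CPM, with each point a library numbered by replicate. Fibroblasts lie between 110 and 142 on the x axis, while all bESC libraries lie under 0 and the 3 SCNT libraries lie lowest there and on the y axis.

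The first comparison asked how bESC lines differ from fibroblasts. At adjusted p under 0.05 in edgeR, 6405 of 13800 genes differed between the IVF and SCNT lines together and the fibroblasts, 3146 of them higher and 3259 lower in the bESC lines. Among these, 4547 differed by more than 1 on the log2 scale. A set of 115 genes was expressed at 10 CPM or more in all 6 IVF and SCNT lines and stayed at or under 3 counts in all 3 fibroblast libraries, and 112 of these were also expressed in the PAR line. In the opposite direction, 59 genes were expressed in all 3 fibroblast libraries and at the floor in all 6 lines, 56 of them also in PAR. By contrast, 6284 genes reached 10 CPM in all 10 libraries.

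ENSBTAG00000023372 had 483 ± 93.2 CPM (SD, n = 6) in the IVF and SCNT lines and 420 CPM in PAR. It had 0 counts in the fibroblasts, which makes it about 889-fold higher or more in the 6 lines against a floor of 3 counts over the group (edgeR adjusted p = 7.30e-07). Means here were TMM-scaled and floors were not, so these folds are approximate. ENSBTAG00000055022 also had 0 counts in the fibroblasts and reached 1682 to 3698 CPM in 5 of the 6 lines and 2176 CPM in PAR. It had only 4.81 CPM in SCNT line 1 (about 4300-fold higher or more on the mean of the 6 lines, edgeR adjusted p = 0.0151). Among genes lower in bESC, ENSBTAG00000015844 had 0 counts in all 7 bESC lines and 170, 167 and 495 CPM in fibroblast replicates 1, 2 and 3 (at least 979-fold lower in the 6 lines, edgeR adjusted p = 7.94e-04). ENSBTAG00000017312 had 0 counts in the same lines and 13.9, 525 and 995 CPM in the fibroblasts (at least 1805-fold lower, edgeR adjusted p = 0.0180). The call for ENSBTAG00000055022 ended with limma-voom (adjusted p = 0.257), without the filter (0.0530) and without fibroblast replicate 2 (0.0514) or 3 (0.0629), over a range of 1.41e-12 to 0.257 for its alternatives. That for ENSBTAG00000017312 ended only without the filter (adjusted p = 0.103, range 9.93e-05 to 0.103), among the alternatives in which it was tested.

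Taken separately, IVF lines differed from fibroblasts at 4933 genes (2600 higher, 2333 lower) and SCNT lines at 5853 genes (2916 higher, 2937 lower). Genes called in both with the same sign numbered 4404, of which 2272 were higher and 2132 lower, and 0 had opposite signs. Independent lists of these sizes would share 549 higher and 497 lower genes. Simulated unchanged groups against the same fibroblasts shared 0.05 genes on average over 20 simulations. In those simulations only 0.1 genes on average were called in each comparison alone. With so few calls, the simulated overlap cannot show how many of the 4404 genes come from the shared fibroblasts. Fold changes of the 2 comparisons correlated at 0.930 across genes, where the simulations gave 0.504. Their covariance was 4.83 against a simulated 0.273. The simulated groups shared the fibroblast libraries too, and their covariance ran only from 0.262 to 0.291. This argues against the shared controls as the source of most of the covariance. The 3 fibroblast libraries could not be split into parts of at least 2, so that part was not measured in the data themselves. With the nuclear donor's fibroblast library alone as the baseline, 3191 genes were called for SCNT.

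Between SCNT and IVF lines, the comparison that asks whether the way the embryo was made marks the line, edgeR called 1 gene of 13800, lower in SCNT. If the SCNT lines share a nuclear donor, as taken below, the way the embryo was made cannot be told apart from that donor's genome. ENSBTAG00000048950 had 70.1 ± 19.01 CPM (SD, n = 3) in IVF and 2.62 ± 0.45 CPM (n = 3) in SCNT lines, a log2 fold change of -4.70 ± 0.35 (SE, adjusted p = 0.00123). The PAR line, at 77.0 CPM, lay within the IVF range, and the fibroblasts lay at 1.21, 2.71 and 1.2 CPM. At an unadjusted p under 0.05, 1075 genes differed, 297 higher and 778 lower in SCNT, where 690 are due by chance at that threshold. With an IVF or SCNT replicate left out, that number ran from 707 to 1144, in fits with fewer samples. The median absolute log2 fold change was 0.28, beside a median standard error of 0.38, and 85.1% of genes lay within 1 on the log2 scale. The 3 values of one group did not overlap those of the other for 19.04% of genes, where chance gives 10%.

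The count of calls depended on the tool and on the libraries in the fit: DESeq2 called 149 genes (29 higher, 120 lower) and edgeR on the 6 IVF and SCNT libraries alone called 62 (35 higher, 27 lower), with ENSBTAG00000048950 in each. The fibroblasts varied more than the lines, at coefficients of variation of 0.490 against 0.252 in IVF and 0.185 in SCNT.

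**Figure D2:**
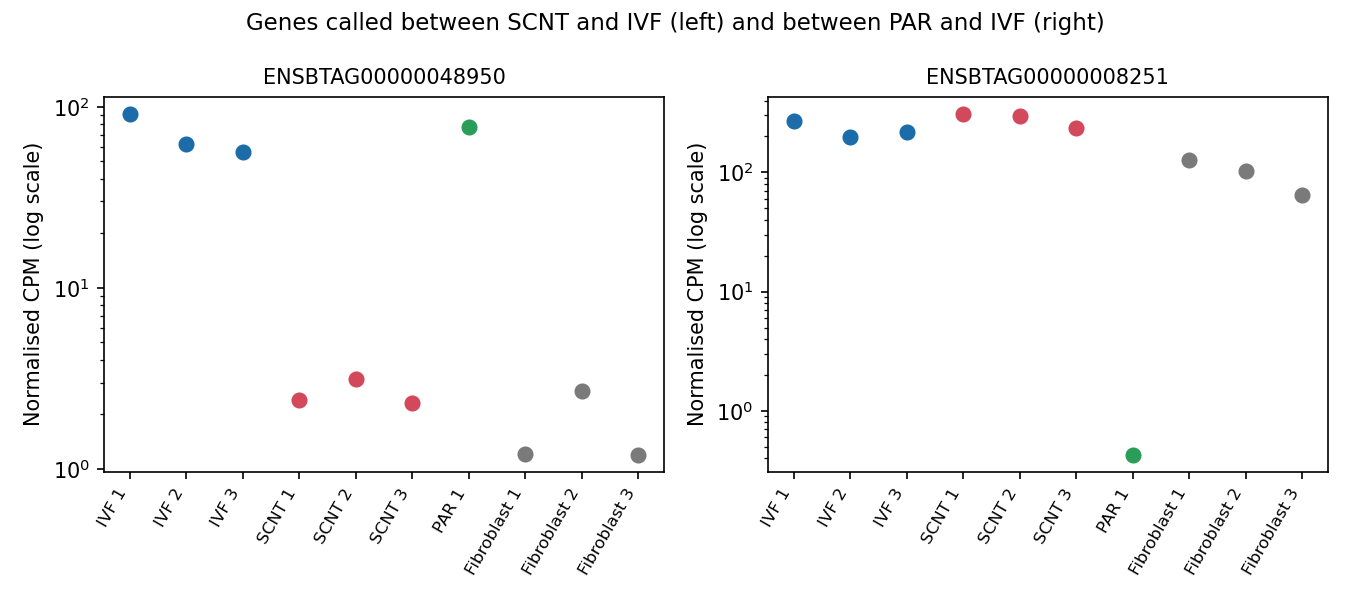
Normalised CPM (y axis, log scale) per library (x axis) of the gene called between SCNT and IVF lines (left) and of the gene called between PAR and IVF lines (right), with 1 point per library. On the left, IVF and PAR libraries lie at 56.4 CPM or more and SCNT and fibroblast libraries at 3.14 CPM or less. On the right, PAR lies at 0.43 CPM and each of the others at 64.8 CPM or more.

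Whether SCNT lines lie nearer to fibroblasts than IVF lines do was asked through the fibroblast score, which is higher where fibroblast genes are higher and bESC genes lower. It was 1.92 ± 0.33 (SD, n = 3) in fibroblasts, -1.31 ± 0.10 (n = 3) in IVF, -1.75 ± 0.11 (n = 3) in SCNT and -1.37 in PAR. The SCNT lines lay 0.43 farther from fibroblasts, a difference of -0.43, and the groups did not overlap (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Most of it lay in fibroblast-high genes, whose mean log2 CPM was 4.00 ± 0.06 in IVF and 3.67 ± 0.11 in SCNT. The bESC-high genes were at 5.32 ± 0.05 and 5.41 ± 0.01. Of the 3259 fibroblast-high genes 71.9% had a lower estimate in SCNT than in IVF, against 32.7% of the 3146 bESC-high genes and 51.5% of the other 7395. With genes chosen by the contrast of fibroblasts against PAR, the difference was -0.44. IVF and SCNT libraries had no weight in that contrast, but they entered the filter, the scaling and the estimate of spread behind it. Fewer genes were detected in each SCNT library than in any IVF library (14042 ± 259 against 14688 ± 317, SD, n = 3 each).

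**Figure D3:**
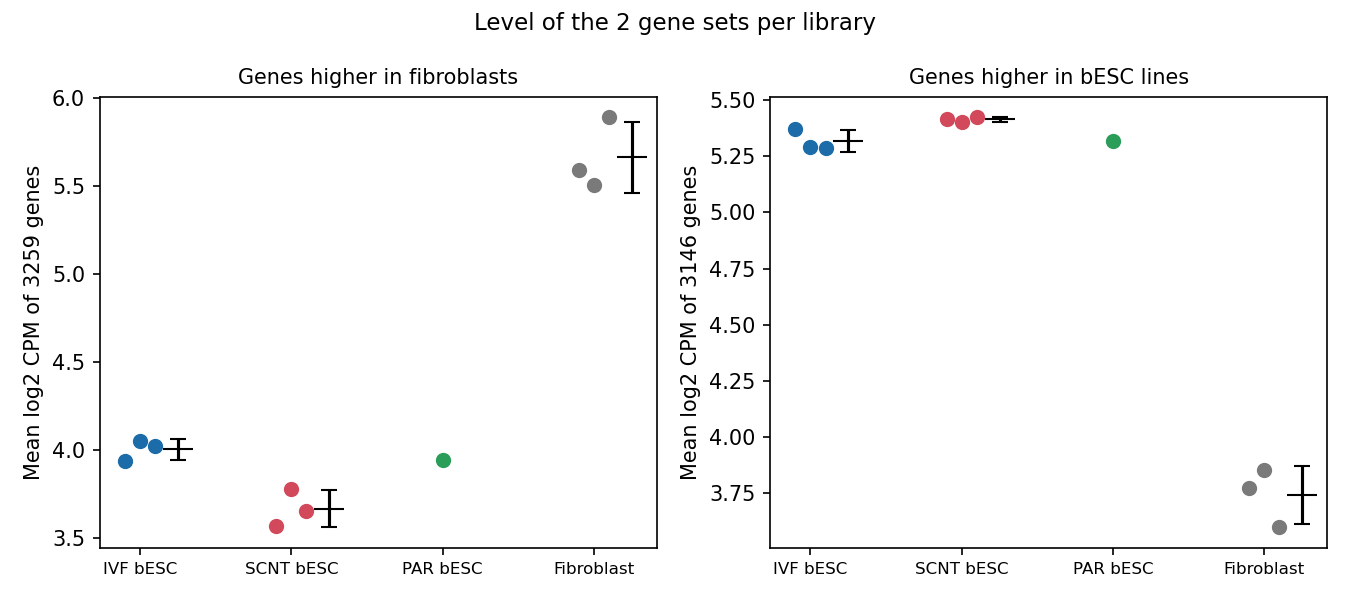
Mean log2 CPM (y axis) of genes higher in fibroblasts (left) and of genes higher in bESC lines (right), with 1 point per library and a bar for the mean and SD of each group with 3 libraries. The 3 SCNT libraries lie below the 3 IVF libraries on the left and above them on the right.

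Genes expressed in the PAR line and at the floor in all 3 fibroblast libraries numbered 239. Of these, 74.1% ± 3.0 (SD, n = 3) were expressed in IVF lines and 72.0% ± 4.7 (n = 3) in SCNT lines (exact permutation p = 0.6). Another 134 genes were expressed in all fibroblast libraries and at the floor in PAR. The share of them at the floor was 65.2% ± 4.1 (n = 3) in IVF and 82.3% ± 8.6 (n = 3) in SCNT lines (exact permutation p = 0.1, the smallest possible). Fibroblast replicate 1 was taken as the nuclear donor of the SCNT lines, from the series text read with the sample list, and 43 genes were expressed in it and at the floor in the other 2 fibroblast libraries. IVF lines expressed 32.6% ± 2.3 (n = 3) of these and SCNT lines 41.9% ± 8.1 (n = 3, exact permutation p = 0.1). SCNT line 2 reached 51.2%, while SCNT lines 1 and 3 stood at 37.2% each. The share of the 43 genes at the floor was 44.2% ± 4.7 (n = 3) in IVF and 38.0% ± 8.8 (n = 3) in SCNT lines (exact permutation p = 0.5). The shares compared here were among 6 computed. None passes 0.05 after adjustment, since 3 against 3 cannot go below 0.1.

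The last comparison set the PAR line, which has no paternal genome, against the IVF lines. ENSBTAG00000008251 was the 1 gene called by edgeR, with 1 count (0.43 CPM) in PAR and 228 ± 35.8 CPM (SD, n = 3) in IVF, a log2 fold change of -8.82 ± 0.68 (SE, adjusted p = 0.00199). The ratio of IVF to PAR was 522, with a 95% exact Poisson interval of 93.5 to 20630. SCNT lines had 236 to 311 CPM and fibroblasts 64.8 to 126 CPM, the lowest of these in the female culture. At an unadjusted p under 0.05, 287 genes differed, fewer than the 690 due by chance at that threshold. When each bESC line was set in turn against the other 6, edgeR called 2 genes for PAR, 1 for SCNT line 1 and 0 for each of the other 5 lines, which at an unadjusted p under 0.05 gave 165 to 721 genes. With limma-voom the call was lost (adjusted p = 0.276, range 8.44e-06 to 0.276 over the alternatives) and 0 genes were called, where DESeq2 called 6. Origin, sex and passage all differed between this line and the IVF lines.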

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

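The test of the difference below was planned, and the gene was chosen by the rule for named genes. ENSBTAG00000048950 stood out because the effect against fibroblasts differed between the 2 kinds of line. It was 5.28 higher in IVF lines than in fibroblasts on the log2 scale (edgeR adjusted p = 1.86e-05) and 0.58 higher in SCNT lines (adjusted p = 0.431). The difference of these effects was -4.70, with an edgeR adjusted p of 0.00123. Since the fibroblasts are shared, this is the same test as SCNT against IVF in the report, not further evidence. Counts were 164, 123 and 102 in the IVF lines, 4, 6 and 4 in the SCNT lines, 177 in PAR and 2, 5 and 2 in the fibroblasts. The call held in each of the 12 alternatives run, with adjusted p from 2.61e-15 to 0.0361.

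With 3 lines against 3 there are 10 splits, too few for a share under 0.05. The real split of SCNT and IVF lines called 1 gene and the highest of the other splits called 0. For IVF lines against fibroblasts these numbers were 4933 and 0, and for SCNT lines against fibroblasts 5853 and 0, with 1 of 10 splits as large in each case. For the 6 lines against the 3 fibroblasts, 1 of 84 splits, the real one, was as large (6413 genes with the lines as 1 group, 1 gene in the highest other split), which excludes chance at 0.05.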

How the results depend on the processing

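No named gene and no score difference changed sign under the alternatives run, and most counts stayed within 1.5 times. For SCNT against IVF (1 gene), DESeq2 called 149 genes, the fit of only the groups compared 62, no filter 2, and leaving out a replicate 1 to 2 (2 without IVF replicate 1 or 3 or SCNT replicate 1). For PAR against IVF (1 gene), DESeq2 called 6, limma-voom 0, only the groups compared 3, and leaving out an IVF replicate 1 to 3 (3 without replicate 3). For SCNT against fibroblasts, the donor library alone gave 3191 genes in place of 5853, with a single control library in the test. The difference in fibroblast score was -0.58 with genes over 2 on the log2 scale, and -0.57 to -0.38 with a replicate left out, the former without SCNT replicate 2. The cause of the other changes was not tested. Fewer samples enter the fits that leave libraries out.

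Lines with the same replicate number did not deviate together: correlations between IVF and SCNT lines were -0.05, -0.08 and 0.24, and not every line correlated best with its own number. The replicate block, fitted to only the groups compared, gave 387 calls for SCNT against IVF (107 higher, 280 lower) and 2629 for IVF against fibroblasts. Fits of only those groups without the block gave 62 and 3952. For SCNT against IVF, calls thus went from 1 in the main fit to 62 with fewer groups, and from 62 to 387 with the block. For IVF against fibroblasts they went from 4933 to 3952 and from 3952 to 2629. Both steps moved the counts, and the block made the larger move in each. No other count moved by over 1.5 times with the block. The gene list tests, with an estimated correlation or with fry, were not run, because the IDs had no symbols. ENSBTAG00000015844 and ENSBTAG00000017312 were not tested when a fibroblast library was left out, since they then fell under the filter. Depth limits calls near the floor: 3 counts stand for 1.34 to 1.84 CPM.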

Other observations

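The comparisons of the fibroblast score and of PAR with IVF were planned, and the tests of explanations for them were chosen after counts of calls, correlations and principal components had been seen. Those on fibroblast RNA as a share of the IVF cultures, on the depth of the PAR library and on genes silent in SCNT lines were chosen after related results had been seen. SCNT line 1 had 6 genes at the floor that were expressed at 10 CPM or more in each of the other 6 bESC lines. PAR had 4 such genes, SCNT line 2 had 1 and the other 4 lines had 0. All 6 of those in SCNT line 1 were expressed in the fibroblasts, at 18.8 to 2578 CPM.

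The IVF lines lay nearer to the fibroblast profile than the SCNT lines: summed over 102 abundant fibroblast genes, IVF lines held 2.14% to 2.27% of the fibroblast level, PAR 1.84% and SCNT lines 0.39% to 0.97%. With the share of reads outside genes as a covariate, 0.938 ± 0.275 (SE) of the difference in score was left. Most of the difference thus remained in the estimate, but so few libraries with that SE cannot settle this source. For the donor's genotype, 593 genes of the score at an unadjusted p under 0.05 between SCNT and IVF lines were taken. Only genes with a mean of at least 1 CPM in the fibroblasts entered. The donor differed from the other fibroblasts with the sign of SCNT minus IVF for 51.8% of them (95% interval 47.7% to 55.9%, under the bound set before the test was run), and for 51.5% of the score's other genes. The donor's difference thus did not recur between the lines. Genotype stays open, since a single donor library of another cell type need not show its effect in bESC lines, and the interval treats genes as independent. Fibroblast-like cells or feeder RNA in the IVF cultures may account for part. Of the 102 genes, 66.7% were higher in IVF than in SCNT lines (95% interval 56.6% to 75.7%, treating genes as independent). Among all 3259 fibroblast-high genes 71.9% had a lower estimate in SCNT, so the abundant ones did not stand out. The 102 genes were chosen in bovine fibroblasts, so RNA of the mouse feeders was not tested directly. The 1.502% of fibroblast RNA needed in the IVF cultures would give 42.2% of the difference in fibroblast-high genes (34.9% to 53.4% over its SE). An earlier test, replaced after its result was seen because it did not ask how much of the difference the share gives, went with this source: 4 of the 102 genes lay far under the IVF level that share would need, of 55 deep enough to show it. Those 4 genes went the other way, and 9 of the 102 were at 0 in the 3 IVF libraries, beside 13 in the 3 SCNT libraries. The tests leave fibroblast-like cells and feeder RNA open, though the protocol says that feeder cells were removed. They also leave open a difference between embryos of the 2 kinds, which was not tested beyond the groups.

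Genes at the floor in the PAR line alone numbered 4. Depth is argued against, since the PAR library was 1.19 times as deep as the next bESC library or more. The female sex of the line stays open: 1 of the 4 genes was at the floor in the female fibroblasts and over it in both male ones, and all 4 were lowest in the female culture, but that is a single library of another cell type. Spread between lines stays open too, as SCNT line 1 had 6 genes at the floor in that line alone. These fell to between 11.5 and 40.5 CPM in at least 1 other line, where 2 of the PAR genes kept at least 292 and 208 CPM. Those CPM were scaled by library totals alone. On TMM-scaled CPM, SCNT line 1 also had ENSBTAG00000055022 at 4.81, a gene at 1682 or more in each of the other 6 lines. ENSBTAG00000003212, chosen after its values were seen, had 1 count in PAR and a mean of 440 CPM in the other lines (edgeR adjusted p against IVF = 0.289), and a candidate explanation, that such genes are expressed only from the paternal copy, which PAR cells lack, was not tested, because the IDs had no names.

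Of the 239 genes expressed in PAR and at the floor in fibroblasts, 5 were at the floor in all 3 SCNT lines and 0 in all 3 IVF lines. Shallow counting in the SCNT libraries stays open: over all 239 genes, Poisson counting alone would put 0.858 genes at the floor in all 3 SCNT libraries at the mean CPM of the IVF lines, but 6.78 at that of IVF line 1. Grouping by chance stays open, because 1 of the 20 sets of 3 lines, the SCNT set, had as many, while 3 sets with IVF line 1 and 2 SCNT lines had 4 each. In edgeR over all libraries 0 of the 5 were called between SCNT and IVF lines, and in the fit of those 6 libraries alone 1 was (adjusted p = 0.0162, with 28, 25 and 13 counts in the IVF lines and 0 in the SCNT lines).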
